A study of Mus musculus with 576 samples.

How the data were processed

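The series holds 576 wells of cells from mouse embryonic stomach at E13.5, and every well has its own table of counts. Per the labels' protocols, stomachs were pooled from embryos of mixed C57BL/6 and CD1 background and dissociated with collagenase. Cells without DAPI stain were then sorted into wells with EpCAM (described as epithelial) or without it (described as mesenchymal). Sample titles mark each well E or M without spelling the letters out, and they give the number of cells sorted into it, the batch, the plate and the well. Here E and M are kept as labels, and the genes measured in each are given below. Each label has 276 wells of 1 cell, 6 wells of 10 cells and 6 wells of 0 cells, spread over 2 batches of 3 plates each.

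Per the labels' protocols, ERCC spike-in RNA was added and the cDNA was amplified before sequencing. The protocols name more than 1 library kit, so the kit used for these wells is left open. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 1.8.4, aligned with STAR 2.5.2b to GRCm38, handled with SAMtools 1.5 and counted with featureCounts 1.5.1 of Subread. The deposited values are whole-number counts of reads per gene, without normalization and without molecular identifiers. Each table has 50778 rows, of which 92 are ERCC spike-ins. Of the other 50686 identifiers, 50462 were found in the GENCODE vM21 annotation of GRCm38. The remaining 224 name no gene there and hold 0.0194% of gene reads. The plan left them out, but they stayed in library sizes and were open to filtering and testing like other rows. Strand use in the counting is not stated, so overlapping genes such as Col4a1 and Col4a2 and near-identical copies such as Hba-a1 and Hba-a2 carry uncertain individual counts.

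All choices of test, filter, gene list and cluster setting were written down before the data were examined, except those named here as later. The 10-cell wells were compared with the edgeR 4.0.16 quasi-likelihood F-test (R 4.3.3) on all 12 libraries, with TMM factors, batch as a covariate, default expression filtering and Benjamini-Hochberg adjustment at 0.05. This test called 63 genes higher in E and 108 lower, 171 in all. Later parts give called genes as percent of the 50462 annotated genes, a fixed total for all settings; changes between settings were labelled from the counts themselves. This percent scale was chosen after seeing the data, for a rule on how numbers are printed and not for what the values showed. Adjusted p-values of single genes in the 10-cell comparison come from this test unless another tool is named. Because the labels name no embryo or litter for a well, the spread in this test is between wells of pooled tissue, not between animals. One M library of 10 cells, on plate 6, failed with 174 gene reads; it stayed in the fit as planned, and is left out of the means and SDs given (n = 5 for M). The naming rule asked for 1 direction in all 6 plates, and it was applied to the 5 plates with a pair of usable libraries. Fold changes against a group whose libraries were all at 0 are lower bounds, computed against a floor of 3 reads over that group.

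Named genes of this test are the 10 with the largest fold in each direction among those that passed, with a mean log2 CPM of at least 5 and that shared direction, plus at most 4 passing members of each fixed list, plus Epcam. The 48 lists hold 402 genes: 17 lists of cell type markers, 24 of signalling families and 7 others, namely collagens, laminins, claudins, EMT transcription factors, S phase genes, G2 and M phase genes and dissociation stress genes. Some genes stand in more than 1 list, such as claudins in the epithelial list and collagens in the mesenchymal one. The list of BMP ligands also holds Bmp1, which encodes a protease and not a ligand. Lists with at least 3 measured genes were tested with camera of limma 3.58.1 (preset correlation 0.01, two-sided, Benjamini-Hochberg over 27 lists), again with an estimated correlation, and with fry, which asks whether a list's genes moved one way on balance without comparing it with other genes. On simulated counts for the same 8624 genes, the edgeR step recovered 14.9% of genes changed by 2 on the log2 scale. It recovered 61.2% of those changed by 4 and 87.9% of those changed by 6. Of 8424 unchanged genes it called 10, and these false calls were among 119 calls in all.

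Single-cell wells were kept with at least 100000 reads on genes, at least 2000 genes with a read and at most 20% mitochondrial reads, ERCC reads left out throughout; this kept 249 E wells and 211 M wells of 276 each. No doublet caller was run, since wells were filled by sorting and the titles state the number of cells. That does not rule out wells with more than 1 cell: wells with markers of the other label, and wells whose ERCC share lay more than 3 times under the median of their label and plate, are given in the report. The labels tie no well to an embryo, so each label is 1 sample and no test was made between single-cell wells. Raw counts were summed per label and given as counts scaled to the summed library (CPM) with exact 95% Poisson intervals. Shares of wells with a read were taken after thinning each well to 100000 reads, with exact (Clopper-Pearson) binomial intervals. These intervals, and the upper limits given for counts of 0, cover counting error only, because amplified reads without molecular identifiers are not independent molecules. A gene was called apart between both labels or clusters when it differed at least 4-fold in both batches and reached 10 CPM in the higher one.

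Kept wells of each label were clustered apart with Python 3.11.15, scipy 1.17.1 and leidenalg 0.10.2: ln(1 + counts per 10000), the 2000 most variable genes, centring within batch, 15 principal components, 15 neighbours and Leiden resolution 0.5. Signalling, cell cycle, stress and mitochondrial genes were left out of clustering, so their levels did not define the clusters. Collagens, laminins, claudins and EMT transcription factors stayed in, so their differences between clusters are not independent of the clustering. Some signalling genes, such as Pdgfra, Rspo1 and Erbb3, also stand in the marker lists that named the clusters. Their differences between the named classes are in part built in. A cluster was named "X-like" from fixed markers reaching 10 CPM in 5% of its wells, by the list with the highest mean log2 difference from all wells of the label, and a cluster whose 10 leading genes held more markers of another class than of its own stayed unnamed. How to apply this last condition was settled after the clusters were seen. Joining smooth muscle with mesenchyme, and neurons with neural crest, was decided after seeing the clusters. Between clusters, at most 4 genes per list past the 4-fold rule are named, largest first.

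Alternatives covered the batch term, plate number as a block, DESeq2 1.42.0, other scalings including ERCC reads, other filters, each 10-cell well left out, other limits on genes per well, and other cluster settings. Fits without the failed well combined with another choice, and without a further M well that held epithelial transcripts, were added after seeing the data, as was leaving out single-cell wells with a low ERCC share.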

Results

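The data are RNA sequencing counts from 576 sorted wells of mouse E13.5 stomach, labelled E (sorted with EpCAM, an adhesion molecule on the surface of epithelial cells) or M (sorted without it). The series title names signals that maintain and differentiate the progenitors of the gastric epithelium, so the comparisons concern which signalling genes each label carried, and which cell populations within a label carried them. For each label there were 46 wells of 1 cell on each of 6 plates, 6 wells of 10 cells and 6 wells of 0 cells, over 2 batches of 3 plates. Reads on genes per 10-cell well ran from 734808 to 1579518 in E, with 8995 to 9634 genes read. In 5 of the 6 M wells they ran from 335860 to 1603209, with 6697 to 10589 genes. The M well of plate 6 gave reads on 28 genes, and 99.7% of its reads were ERCC spike-ins, a share within the range of the empty wells. Empty wells had at most 2543 gene reads, and at most 22 genes.

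Of the single-cell wells, 90.2% in E (95% interval 86.1 to 93.5) and 76.4% in M (70.993 to 81.3) passed the limits on reads and genes. For each label 27 wells had too few reads, and 38 M wells and 0 E wells had enough reads but under 2000 genes. The mitochondrial limit removed 0 wells. Kept E wells had a median of 943300 gene reads (166189 to 1939092) and kept M wells 764250 (132966 to 1659256). Median genes per kept well were 3621 in E and 2814 in M, and 3120 and 2443 after thinning to 100000 reads. Batch 2 was deeper than batch 1, with median gene reads of 1234800 against 729590 in E and 979940 against 618780 in M. Epcam itself (ENSMUSG00000045394, GRCm38 chromosome 17, 87635979 to 87651129) reached 10 CPM in 97.2% of kept E wells and in 4.74% of kept M wells (10 wells). At least 3 markers of the opposite list (mesenchyme for E wells, epithelium for M wells) were present in 11 E wells and 18 M wells, and 13 of those 18 belonged to the mesothelium-like cluster described below. A kept E well of plate 6 had 8479 genes (at most 5322 in the other kept E wells), 1.94% ERCC reads against a plate median of 12.1%, and 7 mesenchymal markers at 10 CPM. A kept M well of plate 2 had 5602 genes (at most 5546 in the others) and 9.80% ERCC reads against 45.7%. Whether they held more than 1 cell was not tested, and they stayed in, with 0.405% of E reads and 0.241% of M reads.

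**Figure D1:**
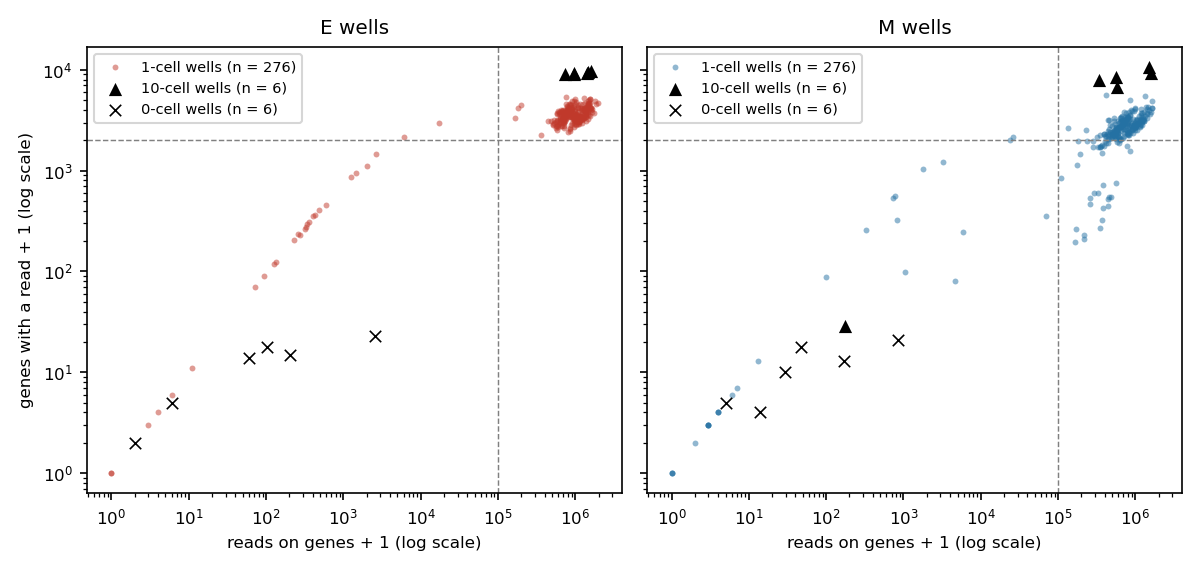
Genes with a read plus 1 (vertical, log axis) against reads on genes plus 1 (horizontal, log axis) for each well, with E and M in separate panels; dots are single-cell wells (46 per label and plate), triangles 10-cell wells (6), crosses 0-cell wells (6), and dashed lines mark 100000 reads and 2000 genes. The M panel shows 38 wells to the right of the read line but under the gene line, and 1 triangle (28 genes) among the empty wells.

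The 10-cell wells asked which genes separate the labels across replicate libraries. E wells carried epithelial keratins, claudins and forestomach squamous markers, and M wells carried collagens, mesenchymal regulators and contractile genes. With 8624 genes tested (edgeR), 63 were higher in E, or 0.125% of the 50462 annotated genes, and 0.214% of the annotated genes were lower. Largest in E were Gstm3, a glutathione transferase (at least 386-fold, 248.5 CPM ± 140.97, SD, n = 6, against 0 in M, n = 5, log2 change 10.90, SE 1.12, adjusted p = 7.709e-05), Ambp, the precursor of a plasma protease inhibitor (at least 308-fold, 199.8 CPM ± 58.3), Upk3bl (at least 242.5-fold), the membrane mucin Muc4 (at least 182.8-fold, 119.1 CPM ± 87.2) and the serine protease Prss8 (at least 159.3-fold). The next were Gpx2, Rab27b, Phgr1, the microvillus protein Pls1 and the alkaline phosphatase Alpl, from at least 148.2-fold down to at least 121.7-fold. This order is that of the full fit. The M library of plate 4 held epithelial transcripts, and without it the claudins Cldn6 and Cldn3 had log2 changes of 13.23 and 11.13. Gstm3 had 10.82 in that setting. Largest in M were Lum, a collagen-binding proteoglycan (ENSMUSG00000036446, chromosome 10, 97565128 to 97572703; at least 1588-fold, 730.01 CPM ± 258.8, SD, n = 5, against 0 in E, n = 6, log2 change −12.27, SE 0.88, adjusted p = 3.628e-06), the tropomyosin Tpm2 (at least 660.4-fold, 263.1 CPM ± 86.5), Pmp22 (at least 495-fold), the potassium channel Kcnj8 (at least 451-fold) and Olfml3 (at least 393-fold). They were followed by Col6a1, Carmn, Fam162b, Cd302 and Col6a2, from at least 267.5-fold down to at least 179.03-fold.

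Among epithelial markers, 5 of 13 measured genes were higher in E and 8 did not pass; adjusted over the list alone, 11 were higher. The passing members included Krt8, an intermediate filament of simple epithelia (1722 CPM ± 397 in E, log2 change 5.44, SE 1.28, adjusted p = 0.0329), Krt19 (1279.6 ± 274.8 against 108.4 ± 136.2, adjusted p = 0.0293), the splicing regulator Esrp1 (log2 change 5.65, adjusted p = 0.0389) and Cldn6 (1335 ± 351 against 86.2 ± 192.7, adjusted p = 0.0475). Epcam, the sorted antigen, was 1212 CPM ± 120.4 in E and 133.3 ± 251.1 in M, with a log2 change of 3.79 (SE 1.12) and an adjusted p of 0.0949, so it did not pass. Its M level came from plate 4 (577 CPM) and plate 3 (89.3 CPM), with 0 in the other 3 usable libraries. Without the plate 4 library its log2 change was 6.44 (adjusted p = 0.00132), and over 25 settings its adjusted p ranged from 3.055e-08 to 0.265 and passed in 6. Claudins, the strands of tight junctions, were higher in 2 of 7 (6 over the list alone), with Cldn3 at 310.4 CPM ± 50.4 against 3.74 ± 8.36 (log2 change 6.26, SE 0.94, adjusted p = 0.000880). Forestomach squamous markers were higher in 3 of 4 (4 over the list alone): the basal keratins Krt15 (835 CPM ± 699.7 against 5.95 ± 13.3, log2 change 8.15, SE 1.03, adjusted p = 0.000148) and Krt5 (at least 71.7-fold, adjusted p = 0.0345), and Trp63, the regulator of stratified epithelia (83.4 ± 64.5 against 0.668 ± 1.49, adjusted p = 0.0345). Glandular stomach markers passed in 0 of 3 (2 higher over the list alone).

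Among mesenchymal markers, 8 of 11 were lower in E (11 over the list alone). They included Col3a1, a fibrillar collagen (15.2 CPM ± 21.3 in E against 1155 ± 192.5 in M, log2 change −6.80, SE 0.91, adjusted p = 0.000240), Barx1, a homeobox regulator of stomach mesenchyme (1.27 ± 3.10 against 177.9 ± 60.1, log2 change −7.08, SE 1.23, adjusted p = 0.00352), and Zeb1 (at least 72.3-fold, adjusted p = 0.0420). Collagens were lower in 7 of 12 (10 over the list alone), with Col6a3 at least 82.8-fold lower (adjusted p = 0.0302). EMT transcription factors were lower in 2 of 3 (3 over the list alone), led by Snai2 (7.78 CPM ± 12.5 against 391.7 ± 148.99, log2 change −6.51, SE 0.95, adjusted p = 0.000593). Contractile genes of smooth muscle were lower in 2 of 6 (5 over the list alone): Acta2 (34.1 CPM ± 30.3 against 956 ± 539, log2 change −4.73, SE 0.92, adjusted p = 0.00779) and Actg2 (6.01 ± 9.60 against 228.2 ± 165.8, adjusted p = 0.0279). Single members of other lists were lower in E: the mesothelial gene Upk3b (at least 123.3-fold, adjusted p = 0.0364), the neuronal RNA-binding protein gene Elavl4 (at least 143.6-fold, adjusted p = 0.0494) and the macrophage gene Lyz2 (at least 399.7-fold, adjusted p = 0.00238). For each of these, 1 of 2 measured list members passed. Over the list alone, 1 mesothelial gene was lower and 1 higher, 1 neuronal gene was lower, with the other fitted above 0, and 2 immune genes were lower. Globin transcripts made up 0.00387% to 28.2% of the gene reads in the 3 M libraries of batch 1, with a median of 7.45%. In M libraries of batch 2 they made up at most 0.00174%. Globin reads count in the totals behind the CPM values.

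Signalling families with a passing member were few in these 12 libraries. BMP ligands were lower in E in 1 of 3 (1 over the list alone), namely Bmp4 (ENSMUSG00000021835, chromosome 14, 46383520 to 46390669; 2.82 CPM ± 4.92 against 205.2 ± 163.7, adjusted p = 0.0494). Hedgehog reception genes were lower in 1 of 4 (1 over the list alone), namely the transcription factor Gli2 (log2 change −7.16, adjusted p = 0.0357). Retinoic acid genes were lower in 1 of 8 (2 lower and 1 higher over the list alone), namely the retinoid-binding protein gene Crabp1 (3.99 CPM ± 6.37 against 200.5 ± 157.5, log2 change −6.43, adjusted p = 0.00939). Laminins were lower in 1 of 6 (1 lower and 1 higher over the list alone), namely Lama2 (at least 154.1-fold, 64.03 CPM ± 33.1 in M, adjusted p = 0.0160). Fgf10, a mesenchymal growth factor and the only FGF ligand measured, was at least 113.98-fold lower (50.7 CPM ± 55.3 in M, adjusted p = 0.0441). BMP antagonists passed in 0 of 4 (2 lower over the list alone), and WNT receptors in 0 of 10 (1 higher over the list alone). In proliferation and stress, 0 of 12 G2 and M phase genes, 0 of 12 S phase genes and 0 of 7 dissociation stress genes passed.

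As groups against the other genes (camera), 4 of 27 lists stood higher in E and 7 lower. The epithelial (adjusted p = 6.072e-17), forestomach squamous (4.852e-07) and claudin lists (2.52e-10) were higher, and the mesenchymal (1.422e-36), smooth muscle (3.246e-10), collagen (1.669e-25) and EMT lists (5.516e-08) were lower. These 7 calls held with an estimated correlation, with adjusted p from 0.00524 to 0.0439, and fry gave adjusted p from 0.000319 to 0.000953. The glandular list was higher (adjusted p = 0.0107), and this call was lost with adjusted p = 0.103 with an estimated correlation. BMP ligands (adjusted p = 0.0405), BMP antagonists (0.0311) and Hedgehog reception genes (0.0405) were lower. With an estimated correlation these had adjusted p = 0.187, 0.103 and 0.176, and leaving out single wells ended each of these calls at least once, with adjusted p up to 0.156, 0.139 and 0.115. In fry, BMP ligands, BMP antagonists and Hedgehog reception genes did not pass (adjusted p = 0.115, 0.0517 and 0.1125), while the glandular list did (0.00248). The lists for WNT ligands, FGF receptors, BMP receptors, TGF-beta receptors, retinoic acid and G2 and M phase genes had camera adjusted p of 0.203, 0.925, 0.910, 0.208, 0.203 and 0.786. Of these lists, fry passed only TGF-beta receptors (adjusted p = 0.0188, with 3 of 3 measured genes fitted above 0). The rest had fry adjusted p from 0.399 to 0.644.

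How many genes were called depended on single M libraries. As percent of annotated genes, 0.0694% were higher and 0.0991% lower without the failed plate 6 well, 0.273% and 0.224% without plate 4, which held epithelial transcripts, 0.0793% and 0.147% without plate 3, and 0.206% and 0.137% without both the failed and the plate 4 well. Of the 43 named genes that passed, 27 still did without the failed well, while Pls1, Esrp1, Krt8, Cldn6, Krt19, Zeb1, Actg2, Upk3b, Elavl4, Krt5, Trp63, Fgf10, Bmp4, Gli2, Col6a3 and Lama2 had adjusted p from 0.0503 to 0.156. With the plate 4 well also left out, some of these passed again in edgeR. They were Krt8 (adjusted p = 1.88e-06), Cldn6 (1.03e-06), Esrp1 (0.0173), Gli2 (0.0245), Bmp4 (0.0292) and Krt19 (0.0354). The rest of them had adjusted p from 0.0597 to 0.146. Scaling by ERCC reads moved the median log2 change of all genes by 0.71 and gave 0.121% higher and 0.0515% lower, and DESeq2 gave 0.668% and 0.386%. All called genes kept their direction in every setting that tested them, 88 of them in the 2 settings with the fewest genes, and in the summed single-cell wells.

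**Figure D2:**
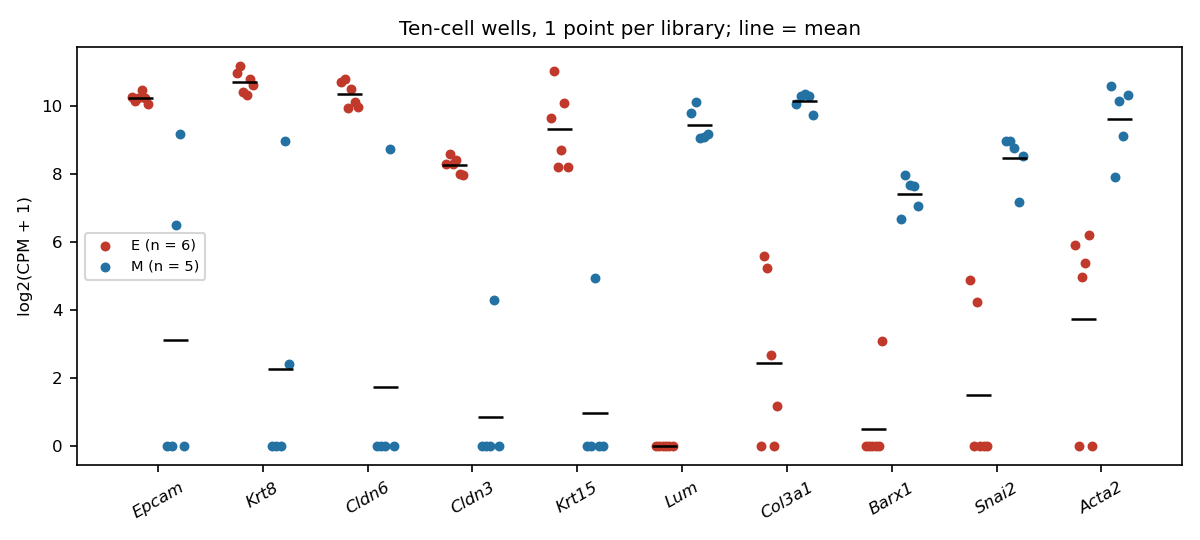
Expression of 10 genes, as log2(CPM + 1), in each 10-cell library of E (n = 6) and M (n = 5, failed well left out), with a line at each mean. Lum was 0 CPM in every E library, and the M library of plate 4 stands above the other M libraries for Epcam (577 CPM), Krt8 (506 CPM) and Cldn6 (431 CPM).

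Whether the difference between labels was itself different in the batches was tested as an interaction in 9710 genes. The edgeR test called 0 genes, with 664 at an unadjusted p under 0.05, and 0 without the failed well (742 unadjusted). DESeq2 called 53 genes (490 unadjusted). Among the largest interaction terms in edgeR were Krt8 (log2 −10.96, adjusted p = 0.143), the haem-pathway gene Fech (6.13, adjusted p = 0.229) and Bmp4 (9.15, adjusted p = 0.229), which did not pass; these 3 were picked after their values were seen.

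The single-cell wells gave the signalling genes of each label at greater summed depth, 243926026 gene reads in E and 170428586 in M. Each label is 1 sample here, so values stand without a test. Epithelial markers were all apart in favour of E (13 of 13, summed 10847 against 345 CPM), with Epcam at 1205 CPM (1201 to 1210) against 18.9 (18.2 to 19.5), log2 ratios 5.46 and 6.44 in batches 1 and 2. Epcam was read in 97.6% of E wells and 4.74% of M wells after thinning (98.4% and 8.53% before). Mesenchymal markers were apart in favour of M in 11 of 11, with Col3a1 at 1188 CPM (1183 to 1194) against 24.4 (23.8 to 24.996) and log2 ratios of −6.51 and −5.15, and Lum at 548 against 1.62 CPM. Smooth muscle (8 of 8), mesothelial (6 of 7), endothelial (3 of 3) and neural crest markers (5 of 6) also stood with M. Neuronal (3 of 4) and immune markers (4 of 8) did so too, and erythroid markers were apart in 0 of 6. Forestomach squamous (4 of 5), glandular (2 of 3) and distal stomach and duodenal markers (4 of 4) stood with E. The last were Nkx6-3, at 42.7 CPM (41.9 to 43.5) against 0, Pdx1, Isx and Cdh17.

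Hedgehog ligands and their reception were on opposite sides. Both ligands above 10 CPM stood with E. Ihh (ENSMUSG00000006538, chromosome 1, 74945315 to 74951672) was at 44.1 CPM (43.3 to 44.9) against 0 (up to 0.0216), 2504-fold over the floor of 3 reads. Shh was at 12.3 CPM against 0.475. Of 9 reception and response genes, 5 stood with M and 0 with E. They included the Hedgehog-binding Hhip (0 against 21.7 CPM, at least 1766-fold), Gli1 (0.201 against 10.98) and Gli2 (0.775 against 29.5). The receptor gene Ptch1 was closer, at 26.1 CPM in E and 58.3 in M. PDGF receptors stood with M in 2 of 2, with Pdgfra at 99.6 CPM (98.1 to 101.1) against 1.81, while 0 of 3 PDGF ligands were apart (Pdgfa 65.3 CPM in E, 26.2 in M).

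WNT ligands stood with M in 2 of 2: Wnt5a at 25.6 CPM (24.9 to 26.4) against 2.55, and Wnt11 at 17.4 against 0.246. Of 12 WNT receptors, Lgr4 (97.9 against 11.7 CPM) and Lgr5, the R-spondin receptor of many epithelial stem cells (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780; 30.6 CPM, 29.9 to 31.3, against 0.440), stood with E and Ror1 with M. Before thinning, Lgr5 had a read in 30.1% of E wells and 29.4% of M wells, and after thinning in 13.7% and 4.27%. Secreted WNT modulators were split. Notum, an enzyme that inactivates WNT proteins (14.3 CPM), and Sfrp5 (13.04 CPM) were read in E against 0 in M, whereas Sfrp1 (167.3 against 2.93 CPM), Sfrp2, Dkk2, Rspo1 and the R-spondin Rspo3 (29.4 against 1.15 CPM) stood with M. Among WNT response genes, Rnf43, a feedback inhibitor, was 42.5 CPM (41.7 to 43.3) in E against 0, at least 2414-fold, Nkd1 stood with M, and the remaining 4 were not apart.

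In the ligand lists, 2 of 4 FGF, 3 of 4 BMP, 2 of 2 TGF-beta and activin and 1 of 2 EGF family genes stood with M. They included Fgf10 (44.4 against 2.00 CPM), Bmp4 (117.5 CPM, 115.9 to 119.1, against 3.46; log2 ratios −7.07 and −3.96), Tgfb2 (105.9 against 9.97) and the neuregulin Nrg1 (14.5 against 0). The 3 genes of the BMP list were Bmp4, Bmp5 and Bmp1, the last of which encodes a protease and not a ligand. The BMP and activin antagonist Fst was 53.6 against 0.730 CPM. In the retinoid list 4 of 10 stood with M, among them the retinoic acid synthetase Aldh1a2 (128.9 CPM, 127.2 to 130.6, against 1.75) and the retinoic acid hydroxylase Cyp26a1 (56.1 against 0.914). Egfr (53.2 against 2.57 CPM) and the Hippo effector Wwtr1 (73.996 against 1.25) stood with M as well. With E stood Fgf20 (14.3 against 0 CPM) and the receptor Fgfr3 (30.7 against 5.74), while Fgfr1 stood with M (36.7 against 5.97) and Fgfr2 was 116.8 against 51.2 CPM. Notch response genes Hey1, Hey2 and Heyl and the ligand Dll1 stood with M. FGF response genes (0 of 4), BMP response genes (0 of 5), G2 and M phase genes (0 of 12) and S phase genes (0 of 12) were not apart. With only the 12 M wells of at least 4000 genes, Nkd1, Dll1 and Egfr turned to E.

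E wells formed 5 clusters. Clusters E3 and E5 (80 wells) were forestomach-like, with Krt15 among their leading genes. Clusters E1 and E4 (81 and 37 wells) were glandular-like, both led by Cym, the gene of the milk-clotting enzyme chymosin; their leading genes held 0 listed glandular markers. The glandular list stood only 0.125 (E1) and 0.1619 (E4) above all E wells on the mean log2 scale, in E4 next to 0.1616 for the enteroendocrine list, of which 2 markers were present against 6 glandular ones. Cluster E2 (51 wells), led by Nepn and Lgals4, carried Pdx1 (64.4 CPM) and Nkx6-3 (185.8 CPM) together with glandular Cldn18. Pdx1 and Nkx6-3 stand in the distal list, which joins distal stomach and duodenal markers. Its members Isx and Cdh17 were also present in E2, and the list does not tell the distal stomach from the duodenum. E2 was left unnamed, since its leading genes held Cldn18 and 0 markers of the distal list. Its own glandular list stood at 0.534 with 6 markers present, so the name glandular-like does not set E1 and E4 apart from E2 by those markers. Of kept E wells, 32.1% were forestomach-like (26.4 to 38.3; batches 30.5% and 33.9%), 47.4% glandular-like (41.1 to 53.8; 48.1% and 46.6%) and 20.5% E2 (15.6 to 26.03; 21.4% and 19.5%). E3 and E4 had the higher totals of G2 and M phase genes, 5193 and 5912 CPM against 696 in E5, 566 in E1 and 1792 in E2.

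Forestomach-like and glandular-like wells differed in 20 list genes (14.6% of those above 10 CPM), 8 higher and 12 lower in the forestomach-like ones. In WNT signalling, Notum was 41.7 CPM (40.3 to 43.1) in forestomach-like wells against 1.70 (log2 ratios 3.75 and 9.54), and the transcription factor Ascl2 10.2 against 0.00869. In contrast, 4 of 12 WNT receptors were lower, among them Lgr5 (5.56 against 60.9 CPM; log2 ratios −2.70 and −6.92), Ror2 (0 against 17.4) and Fzd5 (0.291 against 15.3). Ihh was 0.265 CPM in forestomach-like wells and 62.1 (60.6 to 63.5) in glandular-like ones (log2 ratios −9.10 and −7.36), and Fgf20 was 0 against 24.9, at least 656-fold lower. Shh was 26.5 against 6.36 CPM and did not reach 4-fold in both batches. The activin subunit gene Inhbb (16.6 against 0 CPM), the Notch ligand Jag2 (17.7 against 2.22), the retinoic acid receptor Rarg (19.3 against 2.13) and the laminin Lama3 (13.8 against 0) were higher in forestomach-like wells. Both EMT transcription factors above 10 CPM were also higher there, Snai2 at 19.8 against 0.504 CPM and Zeb2 at 21.1 against 0.252. A single well held 47.3% of the Lama3 reads and 42.2% of those of Jag2.

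E2 differed from the glandular-like wells in 19 list genes (14.8%), 3 higher and 16 lower. Of WNT receptors 2 of 11 were lower and 0 higher, and of WNT response genes 3 of 5 were lower and 1 higher. Lgr5 was 0.261 CPM in E2 against 60.9, and Znrf3, a feedback inhibitor of WNT receptors, was 0 against 34.5 (33.4 to 35.6), at least 572-fold lower. Its relative Rnf43 was 3.19 against 34.3, and Tnfrsf19 was 0 against 18.7, at least 310.1-fold lower. Both Aldh1a1 and Rarb, from the retinoid list, were lower, the retinaldehyde dehydrogenase Aldh1a1 (0.201 against 48.6 CPM) and the receptor Rarb (12.9 against 99.5), and so was the EGF receptor ligand Tgfa (0 against 23.5, at least 390.2-fold). Higher in E2 were the WNT antagonist Sfrp5 (61.9 CPM, 59.7 to 64.1, against 0.869), Ascl2 (13.9 against 0.00869) and Bmp2 (18.6 against 0.139). A single well held 26.7% of the Sfrp5 reads in E2 and 37.6% of those of Bmp2.

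M wells also formed 5 clusters. M1 and M2 (82 and 56 wells) were mesenchyme-like, and M1 was also rich in Acta2 (2562 CPM). The highest list of M1 was smooth muscle, at 0.415 on the mean log2 scale against 0.234 for mesenchyme. Its leading genes held 1 mesenchyme marker and 0 smooth muscle markers. The name of M1 therefore rests on joining these lists, which was decided after the clusters were seen. M3 (42 wells) was neural-like, with Ednrb, the neural crest regulator Sox10 (114.2 CPM), the GDNF receptor Ret (231.4 CPM) and neuronal Elavl4 (571 CPM). M4 (20 wells) was mesothelium-like, with Upk3b (1183 CPM), Wt1 (528 CPM) and Krt19 (1127 CPM); its leading genes held 3 mesothelial markers (Upk3b, Upk1b and Wt1) and 1 listed epithelial marker, Krt19. M5 (11 wells) was immune-like, with C1qb (1685 CPM) and Csf1r (624 CPM), and the stress gene Fos was also among its leading genes. Shares of kept M wells were 65.4% mesenchyme-like (58.6 to 71.8; batches 75.2% and 55.7%), 19.9% neural-like (14.7 to 25.9; 15.2% and 24.5%), 9.48% mesothelium-like (5.89 to 14.3; 7.62% and 11.3%) and 5.21% immune-like (2.63 to 9.14; 1.90% and 8.49%). The sort without EpCAM and the limit of 2000 genes both bear on these shares.

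**Figure D3:**
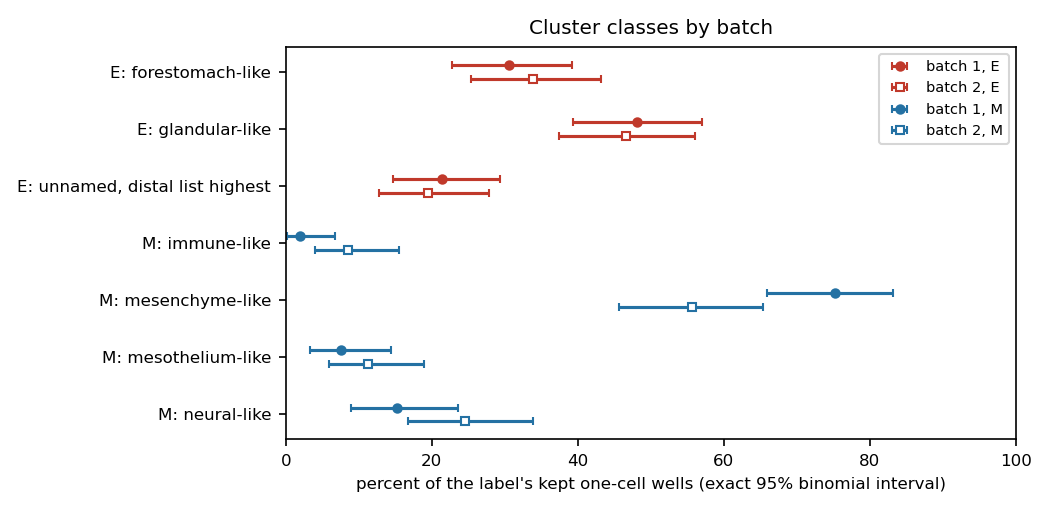
Percent of kept single-cell wells of each label in each cluster class (vertical), by batch (filled points batch 1, open points batch 2), with exact 95% binomial intervals. E classes had close shares in both batches, while mesenchyme-like wells were 75.2% of M wells in batch 1 and 55.7% in batch 2.

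Between the mesenchyme-like clusters, M2 had 21 list genes higher and 6 lower than M1, together 15.976% of those above 10 CPM. M2 carried more of the cycling genes, with 9 of 12 G2 and M phase genes apart (Top2a 515 against 25.8 CPM, Cenpf 313 against 6.82) and 1 of 12 S phase genes (Rrm2). It also carried more Bmp4, at 298 CPM (293 to 302) against 33.8 (32.3 to 35.3), with log2 ratios of 3.68 and 2.15, and more of the Hedgehog reception gene Hhip (59.2 against 9.41 CPM). The TGF-beta co-receptor Eng was 40.3 against 0.0518 CPM, and the WNT modulators Rspo2 (21.9 against 0) and Frzb (16.2 against 0.0173) were higher, with 54.04% and 63.8% of their reads in a single well. Lower in M2 were the BMP antagonist Grem1 (0 against 23.8 CPM, at least 381-fold), Fgf7 (0 against 16.2), the Notch ligand Jag1 (0.479 against 35.3) and Pdgfc (0.354 against 38.9).

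Mesothelium-like wells had 18 list genes higher and 33 lower than mesenchyme-like wells (29.5% of those above 10 CPM). The higher ones included Fgf5 (123.2 CPM, 117.8 to 128.8, against 0, at least 4350-fold), Fgf9 (43.1 against 1.73), Wnt5b (43.3 against 0.953), the R-spondin Rspo1 (148.6 against 8.03), Tgfb2 (370.3 CPM against 44.8), Tgfb3 (88.98 against 3.11) and Pdgfa (118.8 against 17.8). Retinoid genes split, with Aldh1a2 (583 against 119.7 CPM; log2 ratios 2.23 and 2.60) and Crabp1 (685 against 124.4) higher and Cyp26a1 (0 against 88.7) lower. Lower too were PDGF receptors (Pdgfra 0 against 160.2 CPM, at least 851-fold), 5 of 7 EMT transcription factors (Snai2 0 against 629.99, at least 3347-fold), the Hedgehog effector Gli3 (0 against 68.9) and 2 of 3 WNT ligands, among them Wnt5a (0.0627 against 36.7). Of 20 wells in this class, 1 well held 72.9% of the Fgf9 reads and 66.2% of those of Wnt5b.

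Neural-like wells had 9 list genes higher and 49 lower than mesenchyme-like wells (36.2%). Higher were the neuregulin receptor Erbb3 (58.1 CPM, 55.8 to 60.5, against 0, at least 2051-fold), the FGF response genes Dusp6 (392.5 against 55.95; log2 ratios 2.88 and 3.03) and Etv4 (24.1 against 0), Bmp7 (128.6 against 30.1), Notch1 (46.2 against 3.596) and Wwtr1 (191.9 against 44.3). The Notch genes Dll3 (22.3 against 0 CPM) and Hes5 (30.1 against 0) had 58.7% and 73.6% of their reads in a single well. Lower were 5 of 5 WNT modulators, 5 of 8 Hedgehog reception genes (Ptch1 0 against 90.7 CPM, at least 1248-fold), 6 of 10 retinoid genes and 8 of 12 collagens. Bmp4 was 0 against 153.3 CPM, at least 2108-fold lower, and the matricellular Smoc2 0.267 against 421.

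**Figure D4:**
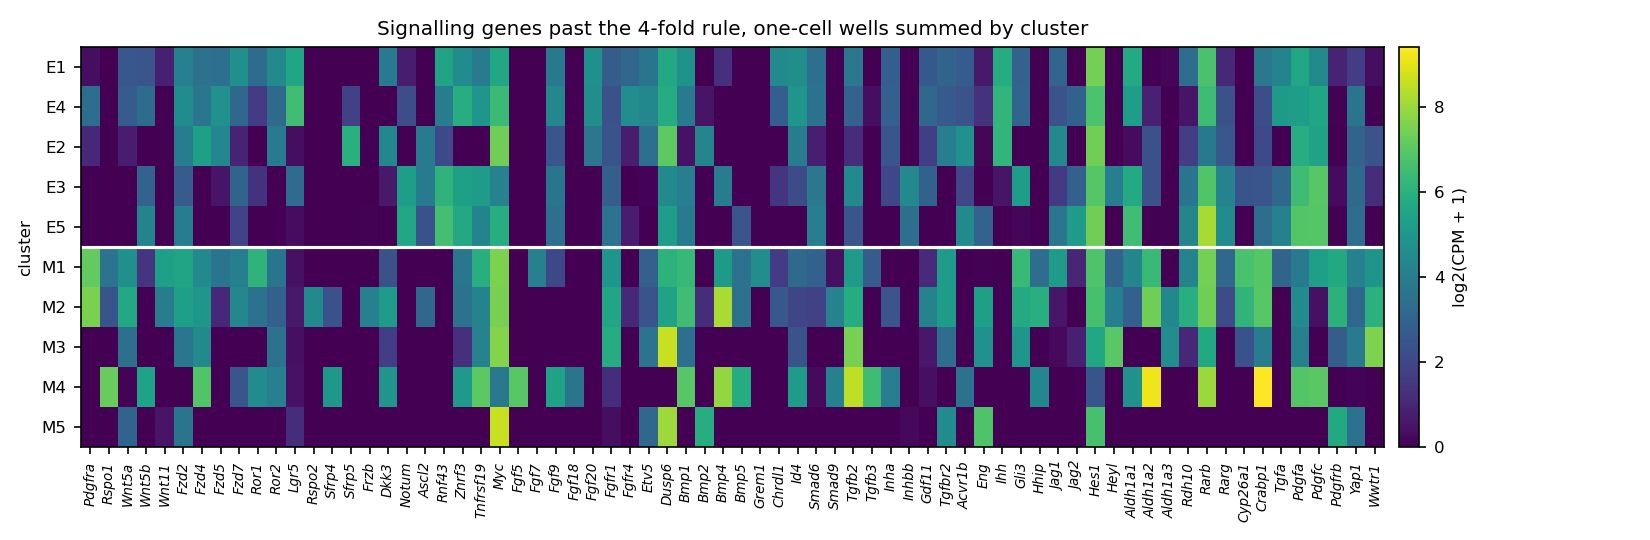
Heat map of log2(CPM + 1) from summed reads of single-cell wells, with 10 clusters (vertical: E1, E4, E2, E3, E5, M1 to M5) and 70 of the named signalling genes past the 4-fold rule in any comparison except the neural-like one (horizontal); brighter cells are higher. Ihh is bright in E1, E4 and E2 and dark in E3, E5 and all M clusters, and Bmp4 is brightest in M2 (298 CPM).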

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

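All tests of explanations in this part were chosen only after the result was seen. The gaps between single wells were found with Dixon's test at 95%, which 17 of 74 groups passed. The 3.7 expected at 1 of 20 assumes normal values, so it is no fair measure here. For Barx1, Gli2, Esrp1, Cldn6, Krt15, Trp63 and Cldn3 all other libraries of the group had 0 CPM. In such a group any library with a read passes.

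The M single-cell wells held a set of wells dominated by globin. Of M wells with enough reads, 21 (8.43%, 5.30 to 12.6) had over 10% of their gene reads on globin genes and 0 had between 1 and 10%; 20 of the 21 fell under the limit of 2000 genes (median 528 genes) and were outside the comparisons, while 1 (15.04% globin) was kept and lies in the M sums of batch 1, where Hba-a1 was 888 CPM against 8.42 in batch 2. Free globin RNA in the sorted drops was argued against, since no E well from the same plates exceeded 0.187% globin, empty wells had 0 globin reads, and Col3a1 was 0 CPM in these wells against 1177 CPM in the other M wells. The candidate explanation left open is erythroid cells in the gate without EpCAM, since the sort as described named only EpCAM and DAPI: the haem synthesis gene Alas2 reached 10 CPM in 90.5% of these wells and 0.877% of the other M wells, while Hba-a1 stood at 246990 CPM and Hbb-bs at 147090 CPM in them, and 11 of the wells kept out came from batch 1 and 9 from batch 2. Biology that could set this share apart from blood left in the tissue was not tested.

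The 10-cell M library of plate 4 held epithelial transcripts. Epcam was 577 CPM there, Krt8 506, Cldn6 431, Cldn3 18.7, Esrp1 11.4 and Trp63 3.34, each far from the other usable M libraries. Of 14 abundant E genes that the other M libraries lacked, 11 (78.6%) reached 10 CPM in it. For any other M library the share was at most 50.0% (2 of 4). The gene set was drawn anew for each library. Sets of the other libraries left out genes that plate 4 carried, so these shares are no like comparison. A wrong label was argued against. M genes present in all other usable M libraries had a median of 0.584 of their mean level in the plate 4 library. In the other M libraries this median was 0.761 to 1.27. A first version of that test, on genes high in the other M libraries on average, gave a median of 0 in this well but also 0, 0.000332 and 6.87e-05 in 3 other M libraries, decided nothing and was replaced after it was seen. Free epithelial RNA across plate 4 was argued against by its single-cell M wells, of which 2.70% had 10 CPM of Epcam, so 1 or more epithelial cells among the 10 may account for the pattern; no biological explanation was tested.

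Chance as the source of the number of called genes in the 10-cell comparison was argued against. Of 100 drawn splits of the 12 wells (of 462), 1, the real one, gave as many genes as were called. The highest other split gave 55. Since the real split was among those drawn, 1 of 100 was the lowest share possible. All splits held the failed well, and the splits do not judge any single called gene.

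The 10-cell M well of plate 6 had 28 genes and 99.653% ERCC reads. Among empty wells, the E well of plate 2 had 2543 gene reads, the E well of plate 5 had 98.99% ERCC reads on few reads, and the M well of plate 6 had 852 gene reads and 99.657% ERCC reads. In E libraries of 10 cells, Krt5 was highest on plate 2 (88.5 CPM), Barx1 on plate 6 (7.60 CPM) and Gli2 on plate 3 (1.05 CPM). In M libraries of 10 cells, Col6a1 was highest on plate 2 (450.3 CPM) and Krt15 on plate 3 (29.8 CPM).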

How the results depend on the processing

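Alternatives that leave out the failed M well together with another choice, or both doubtful M wells, or single-cell wells with a low ERCC share, were chosen after seeing the data; the rest were planned. Genes higher and lower in E, as percent of the 50462 annotated genes (0.125% and 0.214%), became 0.0634% and 0.0535% without a batch term, 0.668% and 0.386% with DESeq2, 0.121% and 0.0515% with ERCC scaling, 0.291% and 0.527% without a filter and 0.0793% and 0.0535% with at least 10 CPM in 6 wells. Leaving out single wells gave 0.0694% to 0.273% higher and 0.0991% to 0.224% lower. Without the failed M well, DESeq2 size factors in edgeR gave 0.0614% and 0.105%, DESeq2 0.575% and 0.793%, and ERCC scaling 0.1704% and 0.0713%; without both the failed and the mixed well it was 0.206% and 0.137%. DESeq2 size factors and total counts in the full set stayed within 1.5 times. Fewer genes were tested without a batch term (6720) and under the stricter filter (6751), and more without a filter (17465); other causes were not tested.

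With plate number as a replicate block, 0.264% of annotated genes were higher and 0.244% lower, against 0.159% and 0.164% when the failed M well was also left out. The shared numbers did not pair the samples: correlations of same-plate E and M deviations ran from 0.00486 to 0.0321 over 6987 genes, and plates 1 and 4 correlated best with their own number. Within each label, single-cell wells at the same plate position in both batches had mean correlations of 0.000405 (E) and 0.002 (M).

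Lists higher in E numbered 3 to 4 in every setting run. Lists lower in E (7) numbered 4 with an estimated correlation and 6 to 11 when single wells were left out. DESeq2 called 53 interaction genes where edgeR called 0. Of 44 named 10-cell genes, 868 of 1052 alternative values kept direction and call, 16.9% lost the call, 6 values gained it and 0 reversed.

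Kept wells moved with the limit on genes: 23.6% of E wells and 4.35% of M wells (12) at 4000 genes, and 83.7% of M wells at 1000. At 4000 genes the epithelial median log2 ratio was 8.33, that of Epcam 9.36, and 3 genes reversed on those 12 M wells, Nkd1 (3.67), Dll1 (3.67) and Egfr (3.75). Of 552 alternative values for single-cell genes between labels, 489 stayed within their spread, 60 moved and 3 reversed.

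Cluster shares moved for glandular-like wells without centring (31.7%), immune-like wells at Leiden resolution 0.3 (0%, with no cluster so named) and in batch 1 (1.90%), and mesenchyme-like wells by batch (75.2% and 55.7%). Without the 2 wells of low ERCC share, 0 genes between labels moved, and 4 between clusters moved further from 0 (Fzd5, Ihh, Cldn18 and Rdh10). Of 2166 values between clusters, 8.59% moved and 6 reversed: with signalling genes left in clustering, Fgf18 (−3.02), Acvr1b (−2.88) and Cldn7 (−1.84), mesothelium-like against mesenchyme-like; Inha without plate 4 (range −3.26 to 9.40 over left-out plates) and Cldn7 without plate 1 (−1.50 to 3.20); and Fosb (1.37), neural-like against mesenchyme-like, at resolution 0.3. In the first class of each comparison, 1 well held 91.2% (Cldn7) or 100% (the others) of these reads; the cause was not tested. The self-test recovered 14.9% of genes changed by 2 on the log2 scale.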

Other observations

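Of the tests of explanations in this part, those on depth and on cycling were chosen only after the result was seen.

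Several genes outside the named comparisons marked E wells. Msln, listed as a mesothelial marker, was read in E rather than M (67.1 against 0.0176 CPM in summed single-cell wells), and stood at 89.02 CPM in glandular-like wells, 116.7 in E2 and 4.12 in forestomach-like wells. Genes of secreted plasma proteins that mark hepatoblasts were also apart in favour of E: Ttr, the thyroxine carrier (110.5 against 0.70997 CPM), the apolipoprotein Apoa1 (122.96 against 2.25 CPM) and Afp (12.03 against 1.29 CPM). In glandular-like wells Ttr was 195.5 CPM and Apoa1 183.9 CPM, against 6.48 and 6.62 CPM in forestomach-like wells, and Afp was 24.9 CPM against 0. Of 2 enteroendocrine genes above 10 CPM, Rfx6 stood with E (19.4 against 0.0117 CPM), while Isl1 was higher in M (174.5 against 48.9 CPM) without reaching 4-fold in both batches. Chga, Chgb and Insm1, under 10 CPM, were read only in M. The pancreatic progenitor genes reached 10 CPM in neither label.

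Stress genes of dissociation were unevenly spread over the M clusters. Their summed level was 15872 CPM in the immune-like wells and 903 to 2439 CPM in the other M clusters, with Fos at 3868 CPM and Egr1 at 2419 CPM in the immune-like wells. Between the labels as wholes, the same list summed to 1783 CPM in E and 2511 CPM in M, and 0 of 9 members were apart.

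In cluster E2, a set of 5 WNT receptor and response genes (Fzd7, Lgr5, Rnf43, Znrf3 and Tnfrsf19) stood lower than in glandular-like wells, and were picked for that. Lower depth of E2 wells was argued against, since shares of wells with a read after thinning lay apart for 3 of the 5 genes (Lgr5, Rnf43 and Znrf3; those of Fzd7 and Tnfrsf19 overlapped), at median reads of 852540 against 945660. A single rich glandular-like well was argued against too, as no well held more than 25.5% of any of these genes' reads. Only the richest well per gene was looked at, so a few wells that together held most reads remain possible. A difference in cycling share was argued against, as all 5 genes were at least 4-fold lower than in E1 (13.8-fold to at least 386-fold). They were also lower than in the cycling cluster E4 (4.71-fold to at least 942-fold). Weaker WNT reception in cells with distal stomach or duodenal genes is a hypothesis that these values may fit. It was found and tested on the same wells. Against it, only 2 of 11 WNT receptors above 10 CPM were apart and Ascl2 (13.9 against 0.00869 CPM) went the opposite way. The WNT antagonist Sfrp5 was higher in E2 (61.9 against 0.869 CPM). Signal strength itself was not measured.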
